A study of Mus musculus with 8 samples.

How the data were processed

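Gene expression was measured in 8 samples of sorted mouse CD4 T cells, 2 in each of 4 groups named naive, CD44lo, CD44hi and Treg (regulatory T cells). Per the labels, the cells came from pooled spleen and lymph nodes of male C57BL/6 mice, and the series title names an Ox40-cre/ROSA-YFP mouse, in which cells that have expressed Ox40 (Tnfrsf4) are marked by YFP. The labels do not give the sort markers or the YFP status of any group beyond the group names. Each sample was hybridized to 1 Agilent mouse array with Cy3 label, after RNA was column-purified with a DNase step and amplified with a linear kit for small inputs.

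The authors' image files had been read with Agilent Feature Extraction 9.5.1.1, per the file headers. The deposited array files hold spot signals as an intensity, with no normalization between arrays. The processed signal among them is background-subtracted and detrended within each array, and the spot means, spot medians and local background medians are raw scanner readings. The remaining columns are flags per spot (unit other, per the file headers). The deposited value table of the authors is on a log2 scale. Its columns had medians between 6.86 and 6.88 and shared their quantiles, and each followed the raw median signal of its array (Spearman correlation across probes 0.9999, probes not being independent replicates), so it was read as quantile-normalized without background subtraction. The authors' processing notes name limma and no further step.

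Every array held 45018 spots, of which 1639 were controls. Spots called outliers by the image software were left out unless they were the only spots of a probe, spots of the same probe were averaged, and 41174 probes remained. Probe names were matched to current symbols, 22951 through an accession, 6659 through the symbol itself and 3109 through an older symbol, while 8455 kept the name in the files. This gave 27670 names, each represented by its brightest probe on average over the 8 arrays. The log2 processed signal minus the array's 75th percentile over non-control probes was used in all comparisons. Genes were tested where this probe was well above background on both arrays of at least 1 group, which left 17996 genes, 13897 of them with a current symbol. The 75th percentile of the processed signal was 639 on naive array 2, 991 on naive array 1 and between 1045 and 1337 on the other 6 arrays.

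Expression was compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes; 4 residual and 2.62 prior degrees of freedom), in 1 fit of all 8 arrays with no block. All 6 pairs of groups were compared, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. A group was set apart by genes called against each of the other groups in the same direction. Values after ± are standard errors of the fit unless named SD. All tests were 2-sided. The labels number the samples of a group 1 and 2 without saying whether these are separate animals, so p-values measure the spread between these samples, which may be technical. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333, so single genes rest on limma's shared spread. In a test on data simulated for Treg against naive alone, with the spread of these arrays and 100 changed genes of each size, limma recovered 60% of genes changed by log2 2 and 2% of genes changed by log2 1, with the right sign in 100% and with 0 unchanged genes called. The adjusted threshold depends on how many genes change, and 3941 were called in the real Treg against naive. These percents therefore do not give the power of the comparisons reported here.

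The 16 gene lists were fixed in advance. They were regulatory T cell genes, effector and memory CD4 genes, naive T cell and quiescence genes, follicular helper T cell genes, T helper cytokines and lineage factors, chemokine receptors and adhesion genes, costimulatory and inhibitory receptors, cell division genes, T cell receptor-induced early genes, interferon-response genes, heat shock and stress genes and apoptosis regulators. The other 4 held markers of further cells that a sort could hold, namely B cell markers, myeloid and dendritic cell markers, CD8 T cell and NK cell markers, and erythroid and platelet markers. The lists held 282 distinct tested genes, 31 of them in 2 or more lists. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over 96 tests (16 lists and 6 comparisons). Camera was also run with the correlation estimated from the residuals, which left 4 degrees of freedom for the estimate. Rotation tests with fry were also run on each list. The directional p of fry tests whether a list's genes move one way on balance, its mixed p whether they change in either direction, and neither compares the list with other genes. Of the 57 list tests called by camera, 43 were also called by the directional test of fry and 56 by the mixed one, and fry called a direction in 2 of the 39 others.

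Named genes followed a rule with these parts. Cd4, Cd44, Tnfrsf4, Foxp3, Il2ra, Il7r and Cd69 were named in every comparison. The 8 genes with the largest change in each direction, among called genes with a symbol whose groups did not overlap, were named for the 3 comparisons with naive and for Treg against CD44hi, and the 3 largest in each direction for the other comparisons. Up to 4 called members with the smallest p were named from each list, and up to 5 genes in each direction from those setting a group apart. Clone and predicted-gene names were left out by this rule, and only part of the genes it takes are printed, since some are not reported here. Where a probe was not well above background on either array of a group, the fold is given as "at least", computed against the lowest signal called well above background on those arrays. Of 188 called results of named genes with another probe on the array, 176 had the other probes on the same side, and the printed exceptions are given beside their genes.

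The groups, the comparisons, the test and its threshold, the lists, the naming rule and the main alternatives were chosen before the data were examined. The alternatives were quantile normalization, normexp background correction (offset 50) with quantile normalization, the authors' value table, no filter on dim probes, a filter requiring all 8 arrays, the mean of a gene's probes, an intensity trend with robust variance, only the groups compared, the slide or the replicate number as an additive term, and leaving out each array in turn. Without 1 array, the lone array of its group is assumed to vary like the other groups. Slide 1 held naive 2, CD44lo 2, CD44hi 1 and Treg 1, and slide 2 the other array of each group. All 57 called list tests had a median of the same sign on both slides and 57 stayed called with the slide as a term. Calls from 2 arrays a group favour a like sign on both slides. Agreement in sign between slides, given below for called genes too, is therefore not separate support. The replicate number was not used as a pair in the comparisons. The same-number correlations of the residuals were 0.259, 0.154, 0.0564, 0.235, 0.259 and 0.332 over the 6 pairs of groups, all above 0, also in the 4 pairs where the number does not follow the slide, so pairing by number is neither shown nor ruled out. With the number as a term 1196, 5397 and 4205 genes were called in CD44lo, CD44hi and Treg against naive. Gene families by name were looked at only after the results were seen. Files were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and, in R, the data.table package (version 1.17.8), and plots drawn with matplotlib 3.10.9.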

Results

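The data were 8 single-colour arrays of mouse CD4 T cells, with 2 arrays for each of the naive, CD44lo, CD44hi and Treg groups. Between 59.2% and 68.8% of the 41174 probes were well above background, with the lowest share on naive array 2 (59.2%) and the next on naive array 1 (62.0%). The 75th percentile of the signal was lowest on naive array 2 (639), against 991 on naive array 1. The naive arrays also differed most from each other, with an SD of the log2 differences of 0.63 across genes against 0.36 to 0.48 for the other pairs. On the first principal component, which held 60.8% of the variance, the naive arrays lay at -99.8 and -104, CD44lo at -22.5 and -5.44, Treg at 42.2 and 50.5, and CD44hi at 65.5 and 73.3. The second component (16.1%) held Treg at 45.7 and 45.5 and CD44hi at -41.2 and -51.4.

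**Figure D1:**
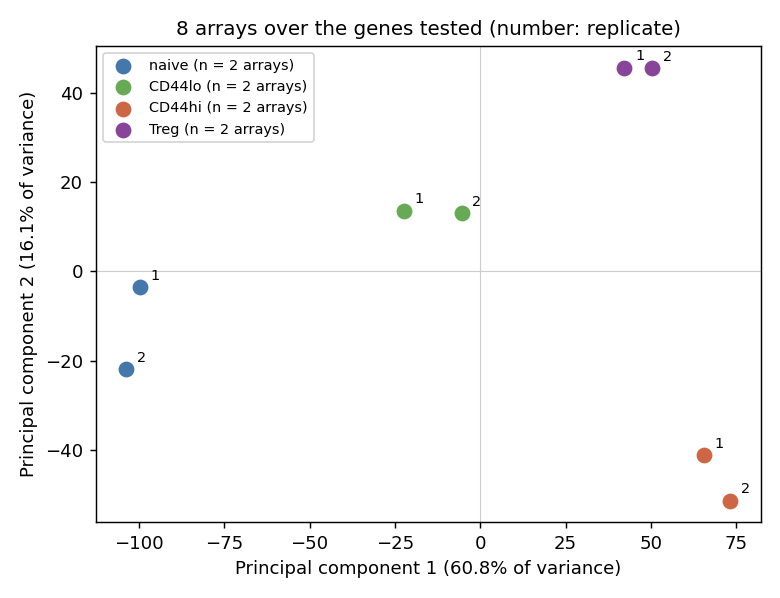
First and second principal components of the 8 arrays over the 17996 genes tested, in arbitrary units, with 1 point per array coloured by group. The naive arrays lie near -100 on the first component, the CD44lo arrays at -22.5 and -5.44, and the CD44hi and Treg arrays above 42.

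Foxp3, the transcription factor that defines regulatory T cells, and Il2ra, the alpha chain of the IL-2 receptor, were highest in Treg and lowest in naive, with CD44lo and CD44hi between. Foxp3 rose over naive by 219-fold (log2 7.77 ± 0.28, adjusted p = 2.5e-05) in Treg, 49.8-fold (log2 5.64 ± 0.28, adjusted p = 1.7e-04) in CD44lo and 29.4-fold (log2 4.88 ± 0.28, adjusted p = 8.0e-05) in CD44hi (SE, n = 2 arrays per group). Its log2 differences within slides 1 and 2 were 7.46 and 8.09 in Treg, 5.52 and 5.76 in CD44lo and 4.44 and 5.31 in CD44hi. Il2ra rose 144-fold in Treg, 14.9-fold in CD44lo and 7.34-fold in CD44hi. Tnfrsf4, which encodes Ox40, the receptor whose promoter drives the cre of the mouse, rose 3.85-fold (log2 1.95 ± 0.30, adjusted p = 0.0138) in CD44lo, 4.57-fold (log2 2.19 ± 0.30, adjusted p = 0.00276) in CD44hi and 11.3-fold (adjusted p = 4.4e-04) in Treg. Its log2 differences within slides 1 and 2 were 1.86 and 2.03, 1.68 and 2.70, and 3.18 and 3.83. Cd44, an adhesion receptor kept high on antigen-experienced T cells, rose 4.36-fold (log2 2.12 ± 0.19, adjusted p = 3.8e-04) over naive in CD44hi, while CD44lo differed from naive by log2 0.62 ± 0.19, adjusted p = 0.141, which was not called. In Treg its brightest probe rose 2.19-fold (log2 1.13 ± 0.19, adjusted p = 0.00665), and 1 of its other 2 probes went the other way. Il7r, the receptor for the survival cytokine IL-7, fell 2.86-fold (log2 -1.52 ± 0.23, adjusted p = 0.00464) in Treg and 1.75-fold (log2 -0.81 ± 0.23, adjusted p = 0.0405) in CD44hi and was not called in CD44lo (adjusted p = 0.176). Cd4 itself was not called in any of the 6 comparisons, and its log2 differences from naive were 0.40 ± 0.50 in CD44lo, 0.48 ± 0.50 in CD44hi and -0.24 ± 0.50 in Treg. Cd69, an early activation marker, was called only in CD44hi against naive among the 6 comparisons, where it fell 2.29-fold (log2 -1.20 ± 0.35, adjusted p = 0.0456).

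**Figure D2:**
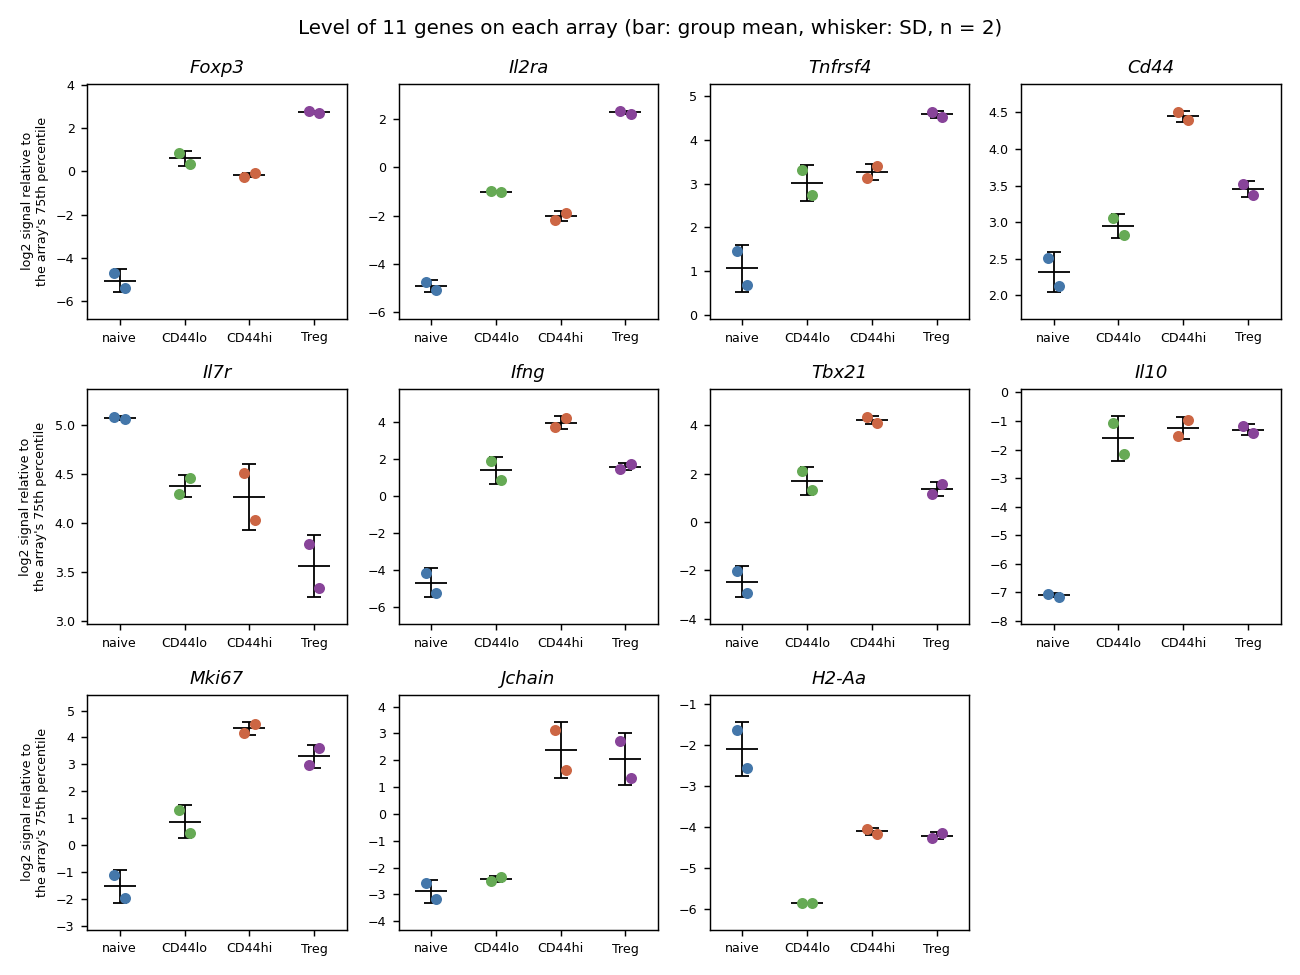
Levels of 11 genes on each array, as log2 signal relative to the array's 75th percentile, with 1 point per array, a bar at the mean and a whisker for the SD (n = 2 per group). Foxp3, Il2ra and Tnfrsf4 are highest in Treg and Cd44 in CD44hi, and Ifng, Tbx21, Il10, Mki67, Jchain and H2-Aa were picked from the named genes after their values were seen.

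The comparison of CD44lo with naive asked how the CD44lo cells differed from naive cells. Regulatory T cell genes were higher, with 22 of 26 tested members higher and 0 lower over all genes and 26 higher when adjusted over the list alone (camera adjusted p = 8.0e-35, and adjusted p = 0.254 with an estimated correlation). The median of the list was 3.84 on slide 1 and 4.12 on slide 2. Among them, Entpd1 (CD39), an ectoenzyme that breaks down extracellular ATP, rose at least 18-fold (adjusted p = 1.1e-04). The inhibitory receptor Ctla4 rose 25.2-fold (log2 4.66 ± 0.22, adjusted p = 1.5e-04) and the cytokine signalling inhibitor Socs2 rose 18.8-fold (log2 4.24 ± 0.14, adjusted p = 7.5e-05). Effector and memory genes were also higher, with 19 of 29 members called up, 0 down, and 23 higher and 1 lower when adjusted over the list alone (adjusted p = 1.4e-24, and adjusted p = 0.254 with an estimated correlation). They included the inflammatory chemokine receptors Cxcr3, which rose 69.2-fold (log2 6.11 ± 0.35, adjusted p = 2.7e-04), and Ccr2, which rose at least 13.8-fold (adjusted p = 6.6e-05). The carboxylesterases Ces2c and Ces2b rose at least 92.4-fold and at least 147-fold, the inhibitory receptor Klrg1 rose at least 48.4-fold and the decoy receptor Il1r2 rose at least 32.4-fold, with adjusted p of 4.1e-05, 4.4e-05, 2.5e-04 and 0.00111.

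The called genes of 5 further lists were higher in CD44lo, but for 1 gene. Of 17 follicular helper T cell genes 8 were higher and 0 lower, and 11 higher and 0 lower when adjusted over the list alone (adjusted p = 8.2e-12, and adjusted p = 0.254 with an estimated correlation). Cxcr5, the receptor that guides cells to B cell follicles, rose 21.4-fold (log2 4.42 ± 0.29, adjusted p = 3.7e-04). The transcription factor Maf rose 21.1-fold (log2 4.40 ± 0.26, adjusted p = 2.8e-04). Of 23 T helper cytokines and lineage factors 12 were higher and 0 lower, with 12 also when adjusted over the list alone (adjusted p = 2.5e-10, and adjusted p = 0.254 with an estimated correlation). The anti-inflammatory cytokine Il10 rose at least 21.4-fold (adjusted p = 4.1e-04). Chemokine receptors and adhesion genes had 12 of 23 higher and 1 lower, and 14 higher and 3 lower adjusted over the list alone (adjusted p = 6.4e-10, and adjusted p = 0.254 with an estimated correlation). Ccr4 rose at least 14.2-fold. Costimulatory and inhibitory receptors had 7 of 22 higher and 0 lower, and 9 higher adjusted over the list alone (adjusted p = 9.2e-08, and adjusted p = 0.254 with an estimated correlation). Lag3 rose 25.4-fold and Pdcd1 rose 12.4-fold. Cell division genes had 5 of 27 higher and 0 lower, and 13 higher adjusted over the list alone (adjusted p = 9.3e-08, and adjusted p = 0.472 with an estimated correlation). The proliferation marker Mki67 rose 5.33-fold and the nucleotide-synthesis enzyme Tk1 rose 7.76-fold.

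Genes that limma called lower in CD44lo than in naive included 3 of a set of 4 class II and invariant chain genes, and single myeloid genes. Cd74, which encodes the class II invariant chain, was the one not called (limma adjusted p = 0.271). The class II genes H2-Aa, H2-Ab1 and H2-Eb1, which present antigen on B cells and dendritic cells, fell 13.4-fold, 11.7-fold and 6.99-fold (log2 -3.75 ± 0.29, -3.55 ± 0.37 and -2.81 ± 0.35). Itgax (CD11c), a dendritic cell integrin, fell 6.31-fold (log2 -2.66 ± 0.20, adjusted p = 6.0e-04) on its brightest probe, while its other probe went the other way, and the paired receptor Pirb fell 11.5-fold. The B cell list as a whole had 2 of 16 members higher and 3 lower (4 and 4 adjusted over the list alone), and Cd22, an inhibitory receptor of B cells, rose at least 56.0-fold. The myeloid and dendritic list had 1 of 17 higher and 2 lower (1 and 2 adjusted over the list alone). The phagocyte oxidase gene Cybb rose at least 26-fold. Of 13 CD8 T cell and NK cell markers 3 were higher and 2 lower (5 and 2 adjusted over the list alone). The cytotoxic protease Gzmb rose at least 19.5-fold and the receptor Klrd1 fell 2.95-fold. Naive and quiescence genes had 0 of 19 higher and 3 lower, and 12 lower adjusted over the list alone (adjusted p = 6.8e-07, and adjusted p = 0.307 with an estimated correlation), among them Txk and Dapl1.

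The remaining lists held few called genes in CD44lo against naive, and camera called none of them or of the B cell, myeloid and CD8 lists. Of 22 T cell receptor-induced early genes 1 was higher and 0 lower (1 and 0 adjusted over the list alone), namely the transcription factor Irf4, up 3.71-fold. Of 23 interferon-response genes 1, Mx1, rose 3.94-fold (2 higher and 0 lower adjusted over the list alone). Of 13 heat shock and stress genes 1, Hspb1, rose 3.76-fold (1 higher and 1 lower adjusted over the list alone). Of 18 apoptosis regulators 2 were higher and 0 lower (2 and 0 adjusted over the list alone), and Pmaip1 rose 4.79-fold. Of 6 erythroid and platelet markers limma called 0, with 0 at an unadjusted p under 0.05. For the early, interferon, apoptosis and CD8 lists the median was below 0 while the mean and the direction of the test were above 0. The directional test of fry did not call the cell division genes (adjusted p = 0.134) and called the CD8 T cell and NK cell markers (adjusted p = 0.0108). In all, 952 genes were called, 815 higher and 137 lower, each with the same sign on both slides, and 792 were called with the slide as a term. The split was 697 higher and 362 lower of 1059 after normexp, and 726 and 307 of 1033 on the authors' table. Without CD44lo array 2 the count was 506, and without naive array 1 it was 7191 (2391 higher, 4800 lower).

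The comparison of CD44hi with naive asked how the CD44-high cells differed from naive cells. Effector and memory genes were higher almost throughout, with 27 of 29 called up and 0 down, and 27 also adjusted over the list alone (adjusted p = 8.1e-25, and adjusted p = 0.254 with an estimated correlation). The median of the list was 4.6 on slide 1 and 5.51 on slide 2. Ifng, the defining cytokine of type 1 helper cells, rose 405-fold (log2 8.66 ± 0.46, adjusted p = 6.4e-05). The cytotoxic granule gene Nkg7 rose 75.7-fold (log2 6.24 ± 0.23, adjusted p = 2.8e-05) and Ccr2 rose at least 112-fold (adjusted p = 1.1e-05). Naive and quiescence genes fell, with 0 of 19 higher and 16 lower (18 lower adjusted over the list alone; adjusted p = 2.6e-09, and adjusted p = 0.254 with an estimated correlation). Igfbp4, an insulin-like growth factor binding protein high in naive T cells, fell 47.5-fold (log2 -5.57 ± 0.25, adjusted p = 4.1e-05). The chromatin organizer Satb1 fell 9.10-fold (log2 -3.19 ± 0.19, adjusted p = 8.8e-05) and the repressor Bach2 fell 7.66-fold (log2 -2.94 ± 0.19, adjusted p = 1.3e-04). The largest rises also included the secreted phosphoprotein Spp1 at least 166-fold, Sostdc1 at least 295-fold and Lrrn3 at least 98.0-fold. Among the largest falls were Tspan9 at 51.2-fold (log2 -5.68 ± 0.21, adjusted p = 2.7e-05) and Ampd1 at 48.7-fold (log2 -5.60 ± 0.29, adjusted p = 6.3e-05).

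Cell division genes rose as a group in CD44hi, with 22 of 27 higher, 0 lower, and 23 higher adjusted over the list alone (adjusted p = 4.6e-17, and adjusted p = 0.261 with an estimated correlation). The mitotic kinase Cdk1 rose at least 68.0-fold and the mitotic cyclin Ccnb2 rose 34.2-fold. Regulatory T cell genes were higher here too, with 22 of 26 up and 1 down (23 and 1 adjusted over the list alone; adjusted p = 1.3e-18, and adjusted p = 0.254 with an estimated correlation). Socs2 rose 49.6-fold and Entpd1 rose at least 31.5-fold. T helper cytokines and lineage factors had 17 of 23 higher and 0 lower (19 and 1 adjusted over the list alone; adjusted p = 1.1e-11, and adjusted p = 0.254 with an estimated correlation). The IL-33 receptor Il1rl1 rose 77.8-fold (log2 6.28 ± 0.22, adjusted p = 2.2e-05), and the nuclear receptor Rora rose 10.8-fold. Follicular helper genes had 14 of 17 higher and 0 lower, with 14 also adjusted over the list alone (adjusted p = 4.5e-11, and adjusted p = 0.254 with an estimated correlation). Cxcr5 rose 35.7-fold. Chemokine receptors and adhesion genes had 16 of 23 higher and 3 lower (17 and 3 adjusted over the list alone; adjusted p = 1.5e-08, and adjusted p = 0.254 with an estimated correlation). Ccr6 rose 189-fold. Costimulatory and inhibitory receptors had 14 of 22 higher and 0 lower, with 14 also adjusted over the list alone (adjusted p = 7.7e-09, and adjusted p = 0.254 with an estimated correlation). Lag3 rose 41.6-fold.

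Of the lists of other cells, camera called only the CD8 T cell and NK cell markers in CD44hi against naive. These CD8 T cell and NK cell markers had 9 of 13 higher and 3 lower (9 and 3 adjusted over the list alone; adjusted p = 4.7e-04, and adjusted p = 0.254 with an estimated correlation). The NK receptors Klrb1c and Klrk1 rose 20.0-fold and at least 10.4-fold. B cell markers had 5 of 16 higher and 3 lower (6 and 3 adjusted over the list alone). Among them Jchain, which joins secreted antibody units, rose 38.7-fold (log2 5.27 ± 0.59, adjusted p = 0.00113) and the B cell receptor component Cd79b rose 6.88-fold (log2 2.78 ± 0.33, adjusted p = 0.00147), while H2-Aa fell 4.01-fold. Myeloid and dendritic markers had 3 of 17 higher and 2 lower (3 and 2 adjusted over the list alone). The lysozyme gene Lyz2 rose 6.36-fold. Early genes went both ways, with 3 of 22 higher and 3 lower (3 and 3 adjusted over the list alone), Irf4 up 6.11-fold, and the transcription factors Jun and Myc down 3.04-fold and 3.68-fold. Interferon-response genes had 6 of 23 higher and 4 lower (6 and 5 adjusted over the list alone). Mx1 rose 12-fold and Oas2 fell 8.00-fold. Apoptosis regulators had 3 of 18 higher and 4 lower (5 and 7 adjusted over the list alone). The survival factor Bcl2 fell 3.53-fold.

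Heat shock genes had 1 of 13 higher, Bag3 at 1.66-fold, and 1 lower, Hspe1 at 1.84-fold, with the same counts adjusted over the list alone. Limma called 0 of 6 erythroid and platelet markers in CD44hi against naive, with 0 at an unadjusted p under 0.05. The early, interferon and myeloid lists differed in sign between the median and the mean or the test, and camera called none of these or of the B cell, heat shock, apoptosis and erythroid lists. The test called 4998 genes, 2383 higher and 2615 lower, all with the same sign on both slides, and 4509 with the slide as a term. The balance turned to more higher than lower genes with the slide as a term (2281 higher, 2228 lower), without the filter on dim probes (1897 and 1232), on the mean of a gene's probes (2351 and 2122) and when only these groups were fitted (1786 and 824 of 2610). It turned without CD44hi array 1 (2057 and 1208 of 3265), without CD44hi array 2 (1657 and 937 of 2594), without naive array 2 (2613 and 2472) and without any 1 of the CD44lo or Treg arrays. It widened the other way without naive array 1 (3317 and 5914 of 9231), after normexp (2569 and 3839), on the authors' table (2638 and 3579) and on quantile-normalized values (2514 and 3485). The same was seen with the filter on all 8 arrays (1611 and 2874) and with an intensity trend (2531 and 3227).

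The comparison of Treg with naive asked which genes mark the regulatory T cells of this sort. All 26 regulatory T cell genes tested were higher, and also when adjusted over the list alone (adjusted p = 2.9e-30, and adjusted p = 0.254 with an estimated correlation). The median of the list was 5.94 on slide 1 and 5.73 on slide 2. Il2ra rose 144-fold (log2 7.17 ± 0.18, adjusted p = 1.0e-05), Foxp3 rose 219-fold, Socs2 rose 179-fold (log2 7.48 ± 0.14, adjusted p = 6.3e-06) and Entpd1 rose at least 63.3-fold (adjusted p = 2.0e-05). The largest rises included Klrg1 at least 364-fold, the guanylate-binding protein gene Gbp2b at least 92.9-fold, the zinc finger gene Plagl1 at least 119-fold and the dynein gene Dnah12 at least 109-fold. For Dnah12, 1 of the other 2 probes went the other way. Naive and quiescence genes had 0 of 19 higher and 16 lower (17 lower adjusted over the list alone; adjusted p = 7.5e-09, and adjusted p = 0.254 with an estimated correlation). Dapl1 fell 32.3-fold (log2 -5.01 ± 0.29, adjusted p = 9.6e-05) and the transcription factor Tcf7 fell 3.12-fold (log2 -1.64 ± 0.15, adjusted p = 5.4e-04). Among the largest falls were Pdlim4 at 115-fold, Ggt5 at 73.2-fold, Klrd1 at 48.4-fold and the phosphodiesterase Pde3b at 27.9-fold.

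Camera also called several other lists higher in Treg than in naive. Effector and memory genes had 23 of 29 higher and 2 lower (23 and 4 adjusted over the list alone; adjusted p = 8.1e-15, and adjusted p = 0.254 with an estimated correlation). Il2rb, a subunit of the IL-2 receptor, rose 31.1-fold (log2 4.96 ± 0.22, adjusted p = 4.0e-05) and Ccr6 rose 206-fold (log2 7.69 ± 0.30, adjusted p = 3.2e-05). Cell division genes had 21 of 27 higher and 0 lower (23 higher adjusted over the list alone; adjusted p = 1.4e-16, and adjusted p = 0.264 with an estimated correlation). Mki67 rose 28.6-fold and Tk1 rose 35.2-fold. T helper cytokines and lineage factors had 13 of 23 higher and 0 lower (16 and 1 adjusted over the list alone; adjusted p = 2.9e-10, and adjusted p = 0.254 with an estimated correlation). Il1rl1 rose 122-fold. Chemokine receptors and adhesion genes had 14 of 23 higher and 3 lower (14 and 4 adjusted over the list alone; adjusted p = 1.2e-08, and adjusted p = 0.254 with an estimated correlation). Costimulatory and inhibitory receptors had 14 of 22 higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 9.3e-08, and adjusted p = 0.254 with an estimated correlation). Ctla4 rose 66.1-fold and Havcr2 (Tim-3) rose 15.9-fold. The 1 lower gene was Cd40lg, the CD40 ligand that helps B cells, at 4.58-fold. Follicular helper genes had 8 of 17 higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 1.7e-05, and adjusted p = 0.437 with an estimated correlation). Maf rose 17.8-fold. Apoptosis regulators had 5 of 18 higher and 2 lower (5 and 2 adjusted over the list alone; adjusted p = 0.0493, and adjusted p = 0.275 with an estimated correlation). This call was lost with the replicate number as a term (adjusted p = 0.0824). The survival factor Bcl2l1 rose 3.52-fold and Pmaip1 rose 8.13-fold.

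CD8 T cell and NK cell markers had 8 of 13 higher and 3 lower in Treg (8 and 3 adjusted over the list alone; adjusted p = 0.00169, and adjusted p = 0.254 with an estimated correlation). Gzmb rose at least 109-fold. B cell markers had 6 of 16 higher and 4 lower (7 and 5 adjusted over the list alone). Cd79b rose 21.1-fold (log2 4.40 ± 0.33, adjusted p = 2.6e-04) and Jchain rose 30.4-fold (log2 4.92 ± 0.59, adjusted p = 0.00176). Myeloid and dendritic markers had 3 of 17 higher and 4 lower (3 and 4 adjusted over the list alone). The Fc receptor Fcgr3 fell 8.33-fold. Early genes had 4 of 22 higher and 1 lower (4 and 1 adjusted over the list alone). Egr2 rose 2.33-fold. Interferon-response genes had 4 of 23 higher and 4 lower (7 and 4 adjusted over the list alone). Oas2 fell 10.1-fold. Of 13 heat shock genes 1, Hspb1, rose 9.80-fold and 0 fell (1 and 0 adjusted over the list alone). Limma called 0 of 6 erythroid and platelet markers, with 0 at an unadjusted p under 0.05. The signs of median, mean and test differed for the interferon, heat shock, B cell, myeloid and erythroid lists, and camera called none of these lists or of the early genes.

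In Treg against naive 3941 genes were called, 2081 higher and 1860 lower, all with the same sign on both slides, and 3364 with the slide as a term. The balance turned to more lower than higher genes after normexp (2184 higher, 2955 lower of 5139), on the authors' table (2213 and 2682) and on quantile-normalized values (2137 and 2462). It also turned with the filter on all 8 arrays (1436 and 2068), with an intensity trend (2188 and 2352) and without naive array 1 (3111 and 6089). The median over all genes was -0.13 in CD44lo, -0.15 in CD44hi and -0.20 in Treg against naive, and for Treg it was -0.10 on the authors' table, a shift of 0.10. Without naive array 1 the median of CD44lo against naive was -0.23, a shift of -0.10. The count for Treg was 2234 without Treg array 1, 1789 without Treg array 2 and 9200 without naive array 1, and 2522 when only these groups were fitted.

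**Figure D3:**
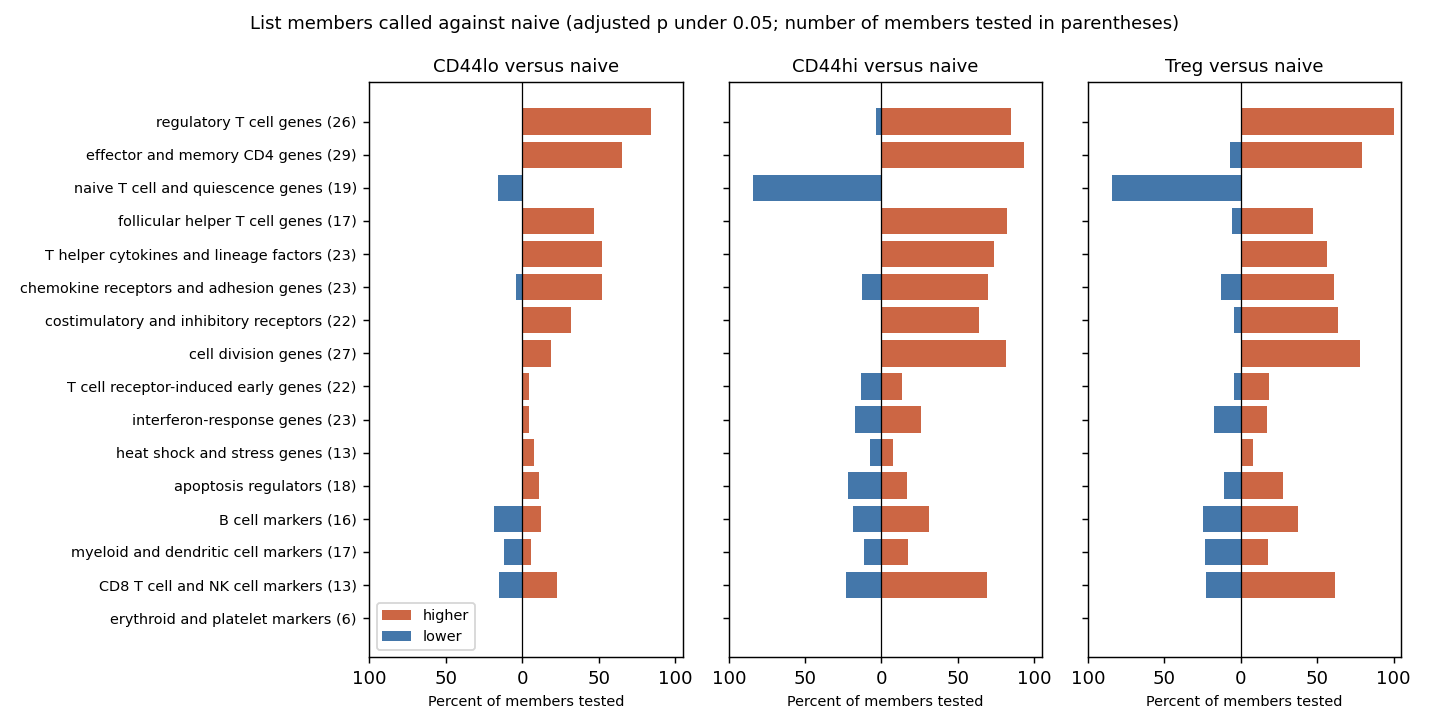
Percent of the tested members of each of the 16 gene lists called higher or lower than in naive, for CD44lo, CD44hi and Treg. Regulatory T cell genes were called higher in 22 of 26 members in CD44lo, 22 in CD44hi and 26 in Treg, and erythroid and platelet markers in 0.

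Set against each other, the changes of CD44hi and Treg from naive overlapped. In both groups 1616 genes were higher and 1158 lower than in naive, 2774 together, where independent lists of these sizes give 276 and 270. Unchanged groups simulated with the same naive arrays shared 0.02 genes on average and at most 1 in 100 simulations. Unchanged groups yield few calls to share, so this does not measure how much of the overlap comes from the shared naive arrays. The log2 differences correlated at 0.835 across genes, which are not independent replicates, against 0.497 in the simulations. Unchanged groups correlate through the shared naive arrays alone, so the 0.497 does not give the part of this sharing in the 0.835. The covariance of the log2 differences was 1.29, against 0.088 in the simulations. At the spread simulated, the shared naive arrays thus gave a small part of the covariance. Ces2c was higher in both, by at least 151-fold in CD44hi and at least 96.5-fold in Treg, and Klrg1 by at least 126-fold and at least 364-fold. Socs2 was higher by 49.6-fold and 179-fold. Opposite changes were called for 71 genes. The higher and lower shares turned to 1547 and 2019 of 3566 after normexp, to 1584 and 1816 of 3400 on the authors' table, to 1620 and 1632 on quantile-normalized values, to 1057 and 1314 with the filter on all 8 arrays and to 2443 and 4738 without naive array 1. The count was 1836 without CD44hi array 2, 1709 without Treg array 1, 1460 without Treg array 2 and 7181 without naive array 1, and 2425 with the slide as a term.

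The comparison of CD44hi with CD44lo asked what separates the CD44-high from the CD44-low cells. Cell division genes rose, with 21 of 27 higher and 0 lower (25 higher adjusted over the list alone; adjusted p = 1.8e-22, and adjusted p = 0.254 with an estimated correlation). The list had medians of 2.60 and 3.77 on slides 1 and 2. Among its members were the cyclin Ccnb2 at 13.1-fold (log2 3.72 ± 0.34, adjusted p = 0.00255) and the ubiquitin-conjugating enzyme Ube2c at 14.0-fold (log2 3.81 ± 0.36, adjusted p = 0.00273). Effector and memory genes had 20 of 29 higher and 0 lower (26 higher adjusted over the list alone; adjusted p = 2.9e-22, and adjusted p = 0.254 with an estimated correlation). The annexin Anxa1 rose 51.2-fold (log2 5.68 ± 0.30, adjusted p = 6.7e-04) and the galectin Lgals3 rose 16.7-fold (log2 4.06 ± 0.23, adjusted p = 7.6e-04). Naive and quiescence genes had 0 of 19 higher and 11 lower (13 lower adjusted over the list alone; adjusted p = 1.2e-09, and adjusted p = 0.254 with an estimated correlation). Igfbp4 fell 29.4-fold (log2 -4.88 ± 0.25, adjusted p = 6.7e-04). Foxp3 differed by log2 -0.76 ± 0.28, adjusted p = 0.166 and Tnfrsf4 by log2 0.25 ± 0.30, adjusted p = 0.695, neither of them called. The regulatory T cell list split into 3 higher and 3 lower of 26 (11 and 3 adjusted over the list alone; adjusted p = 0.0365, and adjusted p = 0.680 with an estimated correlation). Il2ra and the orphan receptor Gpr83 were lower in CD44hi, at 2.04-fold and 4.27-fold, and Socs2 was higher at 2.63-fold. Cd44 itself was higher by 2.83-fold (adjusted p = 0.00535), and Il7r, Cd69 and Cd4 were not called (adjusted p = 0.827, adjusted p = 0.446 and adjusted p = 0.951). The cytokines Il2 and Il17a rose 7.96-fold and at least 13.0-fold, and the skin-homing receptor Ccr10 rose at least 19.3-fold.

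Of the other lists, T helper cytokines and lineage factors had 13 of 23 higher and 0 lower in CD44hi against CD44lo (16 higher adjusted over the list alone; adjusted p = 2.6e-10, and adjusted p = 0.254 with an estimated correlation). Chemokine receptors and adhesion genes had 10 of 23 higher and 2 lower (12 and 3 adjusted over the list alone; adjusted p = 1.5e-05, and adjusted p = 0.254 with an estimated correlation). Costimulatory and inhibitory receptors had 4 of 22 higher and 0 lower (4 adjusted over the list alone; adjusted p = 2.5e-04, and adjusted p = 0.422 with an estimated correlation). Follicular helper genes had 2 of 17 higher, Cd200 and Slamf6, and 0 lower (2 adjusted over the list alone; adjusted p = 2.3e-06, and adjusted p = 0.395 with an estimated correlation). CD8 T cell and NK cell markers had 8 of 13 higher and 1 lower (9 and 3 adjusted over the list alone; adjusted p = 9.7e-05, and adjusted p = 0.254 with an estimated correlation). Klrk1 rose at least 14.3-fold. B cell markers had 4 of 16 higher and 0 lower (7 adjusted over the list alone; adjusted p = 7.2e-04, and adjusted p = 0.437 with an estimated correlation). Jchain rose 28.3-fold and H2-Aa rose 3.35-fold. Myeloid and dendritic markers had 4 of 17 higher and 0 lower (5 and 1 adjusted over the list alone; adjusted p = 0.00103, and adjusted p = 0.481 with an estimated correlation). Lyz2 rose 4.31-fold.

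The 5 lists not called by camera in CD44hi against CD44lo held early genes with 2 of 22 higher and 1 lower (2 and 2 adjusted over the list alone) and interferon-response genes with 2 of 23 higher and 2 lower (4 and 3). They also held heat shock genes with 0 of 13 higher and 1 lower (0 and 1) and apoptosis regulators with 1 of 18 higher and 1 lower (3 and 2). Limma called 0 of 6 erythroid and platelet markers, with 1 at an unadjusted p under 0.05. For the early genes the median was below 0 and the mean above. The directional test of fry did not call the regulatory T cell genes (adjusted p = 0.396), follicular helper genes (0.0575), costimulatory and inhibitory receptors (0.0520), B cell markers (0.109) and myeloid and dendritic markers (0.145). The test of single genes called 1686 genes, 1090 higher and 596 lower, all of the same sign on both slides, and 1386 with the slide as a term. The count fell to 1092 and 793 without CD44hi arrays 1 and 2 and to 513 and 863 without CD44lo arrays 1 and 2, and was 2765 without either naive array.

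The comparison of Treg with CD44lo asked how far the regulatory T cells differed from cells that shared many of their genes. Regulatory T cell genes were higher still in Treg, with 20 of 26 higher and 0 lower (24 higher adjusted over the list alone; adjusted p = 4.7e-26, and adjusted p = 0.254 with an estimated correlation). The medians were 1.59 and 1.95 on slides 1 and 2. Il2ra was higher by 9.61-fold (log2 3.26 ± 0.18, adjusted p = 9.0e-04) and Foxp3 by 4.39-fold (log2 2.13 ± 0.28, adjusted p = 0.0102). Socs2 was higher by 9.51-fold (log2 3.25 ± 0.14, adjusted p = 6.0e-04) and Tnfrsf4 by 2.95-fold (log2 1.56 ± 0.30, adjusted p = 0.0350). Cell division genes had 20 of 27 higher and 0 lower (23 higher adjusted over the list alone; adjusted p = 6.8e-22, and adjusted p = 0.254 with an estimated correlation). Cdk1 rose 7.02-fold. Among the largest falls were Ggt5 at 43.6-fold (log2 -5.45 ± 0.18, adjusted p = 2.3e-04), Pdlim4 at 38.1-fold (log2 -5.25 ± 0.25, adjusted p = 6.8e-04) and Lrrc75b at 22.8-fold (log2 -4.51 ± 0.15, adjusted p = 2.3e-04). The immunoglobulin segments Igkv1-132 and Igkv1-135 were among the largest rises, at least 10-fold and at least 7.03-fold, and Jchain rose 22.2-fold. Il4, the cytokine of type 2 helper cells, was lower by 10.4-fold (log2 -3.38 ± 0.55, adjusted p = 0.0191) and Cd40lg by 4.09-fold (log2 -2.03 ± 0.17, adjusted p = 0.00238). Cd44, Il7r, Cd69 and Cd4 were not called (adjusted p = 0.208, adjusted p = 0.107, adjusted p = 0.724 and adjusted p = 0.586).

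Naive and quiescence genes had 0 of 19 higher and 6 lower in Treg against CD44lo (12 lower adjusted over the list alone; adjusted p = 1.9e-08, and adjusted p = 0.261 with an estimated correlation). Effector and memory genes had 5 of 29 higher and 2 lower (8 and 6 adjusted over the list alone; adjusted p = 0.00601, and adjusted p = 0.725 with an estimated correlation). T helper cytokines and lineage factors had 3 of 23 higher and 1 lower (6 and 2 adjusted over the list alone; adjusted p = 0.00882, and adjusted p = 0.651 with an estimated correlation). Chemokine receptors and adhesion genes had 8 of 23 higher and 1 lower (8 and 3 adjusted over the list alone; adjusted p = 7.5e-04, and adjusted p = 0.254 with an estimated correlation). Costimulatory and inhibitory receptors had 5 of 22 higher and 1 lower (9 and 2 adjusted over the list alone; adjusted p = 4.9e-04, and adjusted p = 0.437 with an estimated correlation). Havcr2 rose 13.3-fold and Tnfrsf9 (4-1BB) rose 3.19-fold. Apoptosis regulators had 1 of 18 higher, Bcl2l1, and 0 lower (3 and 1 adjusted over the list alone; adjusted p = 0.00200, and adjusted p = 0.254 with an estimated correlation). B cell markers had 6 of 16 higher and 1 lower (8 and 2 adjusted over the list alone; adjusted p = 0.00327, and adjusted p = 0.481 with an estimated correlation). Cd79b rose 4.00-fold. CD8 T cell and NK cell markers had 3 of 13 higher and 3 lower (4 and 3 adjusted over the list alone; adjusted p = 0.0261, and adjusted p = 0.357 with an estimated correlation). Klrd1 fell 16.4-fold.

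Camera did not call the other lists in Treg against CD44lo. Follicular helper genes had 1 of 17 higher and 2 lower (1 and 2 adjusted over the list alone), and early genes 1 of 22 higher and 0 lower (1 and 0). Interferon-response genes had 0 of 23 higher and 1 lower (3 and 1), heat shock genes 1 of 13 higher and 0 lower (1 and 0), and myeloid markers 0 of 17 higher and 1 lower (0 and 1). Limma called 0 of 6 erythroid and platelet markers, with 0 at an unadjusted p under 0.05. The early, interferon and erythroid lists differed in sign between the median, the mean and the test. The directional test of fry did not call the effector and memory genes (adjusted p = 0.192), T helper cytokines and lineage factors (0.208), costimulatory and inhibitory receptors (0.0923), B cell markers (0.145) and CD8 T cell and NK cell markers (0.145). The test of single genes called 1001 genes, 665 higher and 336 lower, all of the same sign on both slides, and 783 with the slide as a term. The count was 188 and 457 without CD44lo arrays 1 and 2, 390 and 232 without Treg arrays 1 and 2, and 1641 without either naive array.

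The comparison of Treg with CD44hi asked what separates regulatory T cells from CD44-high cells. Regulatory T cell genes had 13 of 26 higher and 0 lower (21 higher adjusted over the list alone; adjusted p = 3.4e-16, and adjusted p = 0.254 with an estimated correlation). Medians were 1.40 and 1.21 on slides 1 and 2. Il2ra was up 19.6-fold (log2 4.29 ± 0.18, adjusted p = 2.5e-04), Gpr83 up 18.5-fold (log2 4.21 ± 0.16, adjusted p = 2.1e-04), Foxp3 up 7.44-fold (log2 2.90 ± 0.28, adjusted p = 0.00215) and the Ikaros-family gene Ikzf4 up 3.55-fold (log2 1.83 ± 0.14, adjusted p = 9.4e-04). Effector and memory genes were lower, with 0 of 29 higher and 19 lower (1 and 25 adjusted over the list alone; adjusted p = 1.9e-15, and adjusted p = 0.254 with an estimated correlation). The granzyme Gzmk fell 35.3-fold (log2 -5.14 ± 0.49, adjusted p = 0.00213) and the transcriptional regulator Id2 fell 4.75-fold (log2 -2.25 ± 0.14, adjusted p = 5.2e-04). T helper cytokines and lineage factors had 1 of 23 higher and 9 lower (2 and 11 adjusted over the list alone; adjusted p = 9.2e-05, and adjusted p = 0.444 with an estimated correlation). Il4 fell 25.1-fold (log2 -4.65 ± 0.55, adjusted p = 0.00431), Il2 fell 13.4-fold (log2 -3.74 ± 0.29, adjusted p = 0.00103) and Tbx21, which directs type 1 helper cells, fell 7.26-fold (log2 -2.86 ± 0.38, adjusted p = 0.00646). Follicular helper genes had 0 of 17 higher and 6 lower (12 lower adjusted over the list alone; adjusted p = 2.1e-07, and adjusted p = 0.346 with an estimated correlation). The cytokine Il21 fell 15.5-fold and Cd40lg fell 5.82-fold. Cyp26b1, an enzyme that breaks down retinoic acid, was higher in Treg by at least 61.2-fold, and the carnitine and cation transporter Slc22a4 was lower by at least 54.7-fold. Of the genes fixed in advance, Tnfrsf4 was higher by 2.48-fold (log2 1.31 ± 0.30, adjusted p = 0.0491) and Cd44 lower by 1.99-fold (log2 -0.99 ± 0.19, adjusted p = 0.0231). Il7r, Cd69 and Cd4 were not called (adjusted p = 0.132, adjusted p = 0.800 and adjusted p = 0.501).

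In cell division genes limma called 0 of 27 as higher or lower between Treg and CD44hi, with 10 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera down, adjusted p = 7.9e-05, and adjusted p = 0.627 with an estimated correlation). Naive and quiescence genes had 4 of 19 higher and 2 lower (8 and 3 adjusted over the list alone; adjusted p = 0.0386, and adjusted p = 0.725 with an estimated correlation). This call was lost with the replicate number as a term (adjusted p = 0.0592) and on quantile-normalized values (adjusted p = 0.0814). Tcf7 fell 2.06-fold. CD8 T cell and NK cell markers had 0 of 13 higher and 7 lower (3 and 7 adjusted over the list alone; adjusted p = 0.00632, and adjusted p = 0.264 with an estimated correlation). Klrb1c fell 4.97-fold. Apoptosis regulators had 2 of 18 higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.0104, and adjusted p = 0.254 with an estimated correlation). Bcl2 rose 2.60-fold and the death ligand Fasl fell 2.92-fold. Myeloid and dendritic markers had 0 of 17 higher and 1 lower (0 and 1 adjusted over the list alone; adjusted p = 0.00458, and adjusted p = 0.559 with an estimated correlation). The 1 lower gene was Itgax at 2.35-fold, which was well above background on 1 of the 2 Treg arrays.

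Camera did not call the remaining lists between Treg and CD44hi. Chemokine receptors and adhesion genes had 3 of 23 higher and 6 lower (6 and 11 adjusted over the list alone), and costimulatory and inhibitory receptors 4 of 22 higher and 3 lower (8 and 6). Early genes had 2 of 22 higher and 1 lower (3 and 1) and interferon-response genes 3 of 23 higher and 4 lower (5 and 6). Heat shock genes had 1 of 13 higher and 0 lower (1 and 0) and B cell markers 2 of 16 higher and 3 lower (4 and 3). Limma called 0 of 6 erythroid and platelet markers, with 1 at an unadjusted p under 0.05. The costimulatory list had a median and a mean below 0 and a test direction above. The directional test of fry did not call the naive and quiescence genes (adjusted p = 0.134), cell division genes (0.245) and myeloid and dendritic markers (0.188), and called the chemokine receptors and adhesion genes (0.0219). The test of single genes called 1474 genes, 747 higher and 727 lower, all of the same sign on both slides, and 1174 with the slide as a term. The count was 955 and 772 without CD44hi arrays 1 and 2, 535 and 633 without Treg arrays 1 and 2, and 2635 without either naive array. The balance turned under several of these settings, to 394 higher and 561 lower without CD44hi array 1, 246 and 289 without Treg array 1 and 314 and 319 without Treg array 2. It also turned without either CD44lo array (543 and 567), on the mean of a gene's probes (653 and 697), without the filter on dim probes (387 and 389) and with the replicate number as a term (910 and 989).

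Each group was also compared with the other 3 at once. Naive cells stood apart by 861 genes, 102 higher and 759 lower. Among them was Dntt, which adds nucleotides at receptor gene joints in developing lymphocytes. Its mean log2 level was 1.98 ± 0.57 in naive (SD, n = 2), -0.19 ± 0.12 in CD44lo, -2.44 ± 0.058 in CD44hi and -1.53 ± 0.095 in Treg. Ces2c, at background in naive, lay at 0.50 ± 0.35 in CD44lo, 1.21 ± 0.055 in CD44hi and 0.56 ± 0.059 in Treg. CD44hi stood apart by 648 genes, 355 higher and 293 lower. Slc22a4 was higher there than in CD44lo by at least 48.8-fold (adjusted p = 0.00106), and the purinergic receptor P2ry1 was higher than in Treg by at least 47.6-fold. Tspan9, a tetraspanin, lay at -4.23 ± 0.14 in CD44hi against 1.44 ± 0.35 in naive, 0.85 ± 0.16 in CD44lo and -1.26 ± 0.088 in Treg.

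Treg stood apart by 406 genes, 257 higher and 149 lower. The axonemal dynein gene Dnah12 was higher there than in CD44lo by 42.4-fold (log2 5.41 ± 0.21, adjusted p = 3.9e-04) and than in CD44hi by 23.3-fold (log2 4.54 ± 0.21, adjusted p = 2.6e-04). Cyp26b1 was higher than in CD44hi by at least 61.2-fold (adjusted p = 2.1e-04). Lrrc75b was lower than in CD44lo by 22.8-fold (log2 -4.51 ± 0.15, adjusted p = 2.3e-04), and the LIM domain gene Pdlim4 by 38.1-fold (log2 -5.25 ± 0.25, adjusted p = 6.8e-04). CD44lo stood apart by only 7 genes, 6 of them lower. Against naive, Plbd1 was lower by at least 8.80-fold (adjusted p = 0.00242) and H2-Aa by 13.4-fold. Wdfy4 was lower by 9.54-fold (log2 -3.25 ± 0.32, adjusted p = 0.00199) and Rnd3 by at least 4.23-fold (adjusted p = 0.00117). Another lower gene, the ion channel gene Trpm2, and the 1 higher transcript, which has no gene symbol, were outside the naming rule and were chosen after their values were seen.

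The number of genes setting a group apart depended on single arrays. For naive it was 467 without CD44lo array 2, 5600 without naive array 1 and 715 with the slide as a term. The split was 319 higher and 627 lower after normexp and 270 and 653 on the authors' table, and it turned to 3800 higher and 1800 lower without naive array 1. For CD44lo it was 1 without either Treg array, 4 without CD44lo array 1 and 52 without naive array 1. The split of 1 higher and 6 lower turned to 5 and 2 without CD44hi array 2, 3 and 3 without CD44lo array 2, 2 and 2 without CD44lo array 1 and 24 and 28 without naive array 1. It was 3 higher and 15 lower of 18 with the replicate number as a term, 1 higher and 0 lower after normexp, 1 and 1 on quantile-normalized values and on the authors' table, and 7 with the slide as a term. For CD44hi it was 418 and 278 without CD44hi arrays 1 and 2, 271 and 383 without CD44lo arrays 1 and 2, and 264 and 324 without Treg arrays 1 and 2. It was 1032 and 1092 without naive arrays 1 and 2, and 515 with the slide as a term. The split turned to 476 higher and 556 lower without naive array 1, 518 and 574 without naive array 2, 339 and 388 on quantile-normalized values and 198 and 295 with the filter on all 8 arrays. For Treg it was 134 and 120 without Treg arrays 1 and 2, 112 and 187 without CD44lo arrays 1 and 2, 265 without CD44hi array 1, 646 and 688 without naive arrays 1 and 2, and 311 with the slide as a term.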

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

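The gene family alternatives were chosen after the results were seen. Of 386 results of named genes, 0 changed sign where the main or the alternative result was called (the filter on all 8 arrays kept 273 of them). Changes of sign between results called in neither were not counted, such as that of Il7r in CD44hi against CD44lo without CD44hi array 2. Of the 366 called results, 79 lost the call under at least 1 alternative other than leaving out an array and 100 without at least 1 array. All 57 called list tests lost the call with an estimated correlation, 2 with the replicate block and 1 on quantile-normalized values. Of the 11 gene counts, 0 moved by over 1.5 times with the slide as a term, the mean of a gene's probes or an intensity trend. Without the filter on dim probes, which raised the genes tested to 27670, the counts against naive were 606 for CD44lo, 3129 for CD44hi and 2301 for Treg, and 842, 382 and 776 for CD44hi against CD44lo, Treg against CD44lo and Treg against CD44hi. They were 555, 2, 305 and 178 for genes setting naive, CD44lo, CD44hi and Treg apart, and 1644 for genes changed alike. With the filter on all 8 arrays (15279 genes), CD44lo against naive gave 621 and naive apart 570. With only the groups compared, CD44hi and Treg against naive gave 2610 and 2522. CD44lo apart gave 18 with the replicate block, 1 after normexp, and 2 on quantile-normalized values and the authors' table. Treg apart gave 626 after normexp and 614 on the authors' table. The causes of these moves were not tested.

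Without each array in turn the counts ranged from 506 to 7191 for CD44lo against naive, 2594 to 9231 for CD44hi against naive, 1789 to 9200 for Treg against naive, 513 to 2765 for CD44hi against CD44lo, 188 to 1641 for Treg against CD44lo and 535 to 2635 for Treg against CD44hi. Genes apart ranged from 467 to 5600 for naive, 1 to 52 for CD44lo, 264 to 1092 for CD44hi and 112 to 688 for Treg, and genes changed alike from 1460 to 7181. The highest counts of the comparisons against naive came without naive array 1, the brighter of the naive arrays.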

Other observations

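Among the tests in this part, the 2 on mixtures given first for the regulatory T cell genes were set before their results were seen, and the other 6, the other pairs of shares, the gene families and the genes picked out here were chosen afterwards. Of the 2774 genes changed alike in CD44hi and Treg against naive, a choice that favours a place between, CD44lo had a mean between naive and both in 2382, was called in the same direction in 861 and in the opposite direction in 0, by limma. In all 3539 genes had an unadjusted p under 0.05 in CD44lo against naive. Of 172 genes raised at least 16-fold in both CD44hi and Treg and within 2-fold of each other, 67 were not called in CD44lo against naive, and 31 lay within 2-fold of both groups in CD44lo. These 31 included the transcription factor Arnt2 (mean log2 -2.78 in CD44lo, -2.76 in CD44hi and -2.64 in Treg), the protease Mmp9 (-3.07, -3.25 and -2.48) and the signalling regulator Rgs16 (0.84, 1.23 and 1.55, against -3.43 in naive). Another 30 of the 172 lay within 2-fold of naive in CD44lo. Of the 71 genes that went opposite ways in CD44hi and Treg, 45 were lower in CD44hi and higher in Treg. Gata1, a transcription factor of the erythroid line, had log2 -2.09 in CD44hi and 2.41 in Treg against naive, Ecm1 -2.06 and 1.06, and Tlr7, a sensor of single-stranded RNA, -1.90 and 1.46, while Ifitm10 had 2.20 and -1.71.

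Gene families were searched with 25 name patterns, which were chosen after the results were seen and of which 22 held at least 2 genes tested. Of 132 camera tests 70 were called at the preset correlation and 0 with an estimated correlation. Of 80 ribosomal protein genes 45 were lower and 0 higher in CD44hi than in naive (median log2 -0.80, adjusted p = 5.8e-10, and adjusted p = 0.620 with an estimated correlation). Rps19 had log2 -1.42 and Rpl35a -1.35. The direction held under each scaling, with medians of -0.26 on quantile-normalized values (23 lower), -0.29 after normexp (30 lower) and -0.27 on the authors' table (27 lower). The medians of all genes in CD44hi against naive were -0.16, -0.13 and -0.12 there, and -0.15 in the main scaling. The gap between ribosomal protein genes and all genes was therefore much smaller under the other scalings, and its size depends on the scaling. The median of the ribosomal protein genes was -1.13 without naive array 1 and -0.47 without naive array 2. Camera also called them lower in CD44lo (median -0.55, adjusted p = 6.5e-10, and 0.620 with an estimated correlation) and in Treg (median -0.55, adjusted p = 9.9e-06, and 0.722). These medians were smaller on quantile-normalized values (-0.14 in CD44lo and -0.095 in Treg), after normexp (-0.17 and -0.14), on the authors' table (-0.12 and -0.10) and without naive array 2 (-0.21 and -0.22). In Treg the quantile-normalized median was not below that of all genes (-0.14), and neither was the median on the authors' table (-0.10 for all genes). In CD44lo 0 of the 80 were called against naive by limma, with 32 at an unadjusted p under 0.05, and in Treg 4 were lower and 0 higher. Without naive array 1 the lower genes were 75 in CD44lo, 74 in CD44hi and 73 in Treg. Of 17 immunoglobulin gene segments 14 were higher in CD44hi and 12 in Treg than in naive, with 0 lower (medians 4.42 and 3.36, adjusted p = 6.4e-10 and 5.8e-09, and adjusted p = 0.416 and 0.420 with an estimated correlation). The direction held under each scaling, with medians down to 1.66 and 1.28 after normexp. Limma called 0 of the 17 in CD44lo, also with 0 at an unadjusted p under 0.05. Of 18 killer cell lectin-like receptor genes, a family best known from NK cells, 14 were higher and 1 lower in CD44hi and 12 higher and 1 lower in Treg (medians 3.10 and 1.76, adjusted p = 1.7e-08 and 1.7e-05, and adjusted p = 0.377 and 0.424 with an estimated correlation). Their direction held under each scaling, with medians down to 0.54 and 0.30 after normexp, but the higher genes in Treg were 7 after normexp and 8 on the authors' table. In CD44lo 4 were higher and 1 lower.

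Regulatory T cell genes were higher in CD44lo than in naive, and cells of the other groups in that sort are a possible source. With naive-like and regulatory T cells alone, the 232 genes at least 4-fold higher in CD44hi than in naive and Treg would not rise above both, and their median difference of CD44lo from the higher of these was -0.0024 (quartiles -0.56 and 0.78). The bound set in advance for such a mix, a median at or below 0, was met, but with 50% of the genes above 0 it decides nothing. Against such a mix, 17 of them were called higher in CD44lo than in both, over a bound of 1.05 genes that was set afterwards, among them Gzmk, Il4, Tgfb3, Cx3cr1 and S1pr5. With CD44hi-like cells added, the shares from genes leaning to CD44hi (11.8%, 95 genes) and to Treg (11.8%, 44 genes) predicted the 172 genes raised alike with a median observed over predicted ratio of 0.692 (quartiles 0.163 and 2.02, which hold 1), but 72.1% of these genes lay over 2-fold from the prediction, where 17.4% differed as much between the CD44lo arrays, and 41.3% (20 genes above and 51 below) lay on one side under every choice of 1 array per group. This spread goes against 1 pair of shares of these profiles, as measured, for all genes, since no pair of whole percents left fewer than 54.7% over 2-fold away. Far below the prediction lay Jchain (ratio 0.0466) and immunoglobulin segments. Cell division genes such as Birc5 (0.212), Ccna2 (0.213) and Bub1 (0.237) also lay below it, with Tk1 nearer to it (0.747). Far above it lay Cables1 (6.58), Col16a1 (5.57) and Maf (3.72). Genes of such sets may move together, so the 172 genes are not separate pieces of evidence. Plasma cells in the CD44hi and Treg arrays are a candidate source of the Jchain and immunoglobulin signals, as described further on. Such a source would put these genes below a prediction made from shares of T cells. The test was not run without these genes, so it does not weigh against a mix of the T cells alone. The shares are medians over genes with wide quartiles (3.60% and 24.0% for CD44hi, 6.25% and 22.2% for Treg), and Foxp3 alone gave 22.4% of Treg. The genes above in every choice fell from 20 to 6 with the Foxp3 share for Treg and to 2 with the upper quartiles, while those below rose from 51 to 70 and 85, so which side they lie on depends on the shares. A mix with other parts, such as subsets of either group, and a distinct state of the CD44lo cells could each still account for the pattern and were not tested apart.

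Class II genes were higher in naive than in CD44lo by a median log2 of 3.18 over 4 genes. The 4 included Cd74, which encodes the class II invariant chain and was not called by limma (log2 -0.73 in CD44lo against naive, adjusted p = 0.271). B cells in the naive arrays would bring their other transcripts. Yet 10 markers of B cells alone, all also in the fixed B cell list, had a median of -0.24 (quartiles -1.69 and 0.17), which argues against B cells as the whole source. The marker with the brightest probe, Pou2af1, lay at 2.25 in naive and 2.53 in CD44lo, levels that could hide a small share of B cells. Signals of different probes do not rank genes by abundance. For 13 dendritic cell markers, 4 of them in a fixed list, the median was 0.68 (quartiles -0.20 and 2.21), with 4 called higher in naive and 0 in CD44lo. Cst3, the one with the brightest probe, lay at 2.79 in naive and 2.57 in CD44lo. Of the 13 markers, 12 were well above background on both naive arrays and 13 on both CD44lo arrays. Since the markers went both ways, a small share of dendritic cells in the naive sort cannot be told apart from lower expression by CD44lo cells. A sort on CD4 and T cell markers would remove most such cells, but the labels do not give the gate.

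Jchain and immunoglobulin segments were higher in Treg and CD44hi than in naive, by log2 4.92 for Jchain in Treg. On arrays 1 and 2 Jchain lay at 2.72 and 1.35 in Treg, 3.13 and 1.65 in CD44hi and -3.18 and -2.59 in naive. The higher array of Treg and of CD44hi was on slide 1. Plasma cells are a candidate source, since 12 plasma cell markers had a median difference of 0.69 in Treg (quartiles 0.20 and 2.37). Of these markers 0 were in a fixed list and 11 were well above background in naive cells too. Derl3 lay at -5.54 in naive, -2.56 in Treg and -2.63 in CD44hi, and Creld2, the one with the brightest probe, at 3.10, 3.29 and 3.56. In CD44hi the median was 0.74 (quartiles 0.46 and 2.65). In Treg 5 of the 12 were called higher and 1, Fkbp11, lower, in CD44hi 6 higher and 2 lower, and several, such as Xbp1, are also induced in activated T cells. B cells remain open, since 10 markers of B cells alone had a median of -0.43 in Treg (quartiles -0.59 and 2.50; 4 called higher and 1 lower), with Cd79b higher (log2 4.40) and Pou2af1 lower (log2 -1.85). In CD44hi their median was 0.86 (quartiles -0.11 and 2.76; 4 called higher and 0 lower), with Cd79b at log2 2.78 and Pou2af1 at 0.99, which was not called. Against them, H2-Aa, H2-Ab1 and H2-Eb1 were lower than in naive in Treg (log2 -2.12, -1.99 and -1.90), and all 3 were also called lower in CD44hi. A sort on CD4 and the T cell receptor would remove most cells of both types, but the labels do not give the gate.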
